A study of Homo sapiens with 24 samples.

How the data were processed

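Polyadenylated RNA of forebrain progenitors was sequenced from 24 cultures: 3 lines (H9, hiPS10, HS1), 4 days (13 to 16) and 2 differentiation replicates each. Per the labels' protocols, cells were differentiated on laminin-111 in N2 medium with inhibitors of both SMAD pathways. They were replated at day 11 in B27 medium without vitamin A with BDNF, ascorbic acid and a ROCK inhibitor, and given fresh B27 medium after day 14. RNA was isolated with RNeasy columns and libraries were made with a TruSeq RNA kit, per the labels' protocols.

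The deposited files are 3 tables of raw read counts per gene, 1 per line. The authors counted reads with featureCounts from Subread against GENCODE v27 on hg38, by gene name, with read pairs and the reverse strand setting, per the file headers of the hiPS10 and HS1 tables. Alignment with STAR is given by the submitters' processing notes. The H9 table has no such header, but its inputs appear with those of HS1 in the header of the HS1 table, so both were counted in 1 run and hiPS10 in another. The HS1 libraries were used again from an earlier series, per the labels. The tables hold 19 count columns that belong to no sample here, which were left out. In 15 gene names a spreadsheet had written dates, and these were joined by coordinates.

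Of 56609 gene names, 552 (Y-linked genes, XIST, TSIX and HLA genes) were dropped. Biotypes came from GENCODE v44, a later release than the counts used: 35421 names matched by name, 21046 by exon overlap on the same strand and 142 had none. A lincRNA is here a long noncoding RNA gene that overlaps no protein-coding gene. Counts were divided by TMM-scaled totals to give CPM. The replicate pairs were checked for copied libraries (chi-square per gene 23.8 to 236 over 12 pairs) and for strand: 833 genes covered to at least 95% by exons of the other strand held 96 to 268 CPM in sum. The kit is unstranded as sold while reads were counted by strand, and the library strand was not settled further, which leaves values of antisense genes such as ZNF667-AS1 less certain.

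Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and samtools 1.23.1. Genes were kept by edgeR's filter with a minimum count of 10, which left 19062. The edgeR quasi-likelihood test was fitted to the 12 groups of all 24 libraries, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a false discovery rate of 0.05. Contrasts were day 16 against day 13 averaged over lines, each single-day step, each pair of lines averaged over days, and the interaction of line with the change from day 13 to day 16. Each line's day effect was also fitted in its own 8 libraries. Positive log2 differences mean higher at the later day or in the line named first. Lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 33 lists of a comparison. Log2 values for components used a prior count of 2.

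The comparisons, the 33 gene lists, the naming rule and the first set of alternatives were chosen before the data were examined. For the day comparison the 10 protein-coding genes per direction with the largest change at 5 CPM or more and the same sign in all 3 lines are named. For each line pair these are 5 per direction without overlap between lines. Named as well are 3 lincRNAs per direction at 1 CPM or more, up to 4 members per list by adjusted p, and markers of identity, with some results left out. Neighbours of imprinted and zinc finger genes were added after values were seen.

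Whether replicate numbers pair the samples was checked from the correlation, across genes, of the difference between replicates on different days. It was 0.80 to 0.91 in H9 and 0.79 to 0.88 in HS1, but -0.04 to 0.30 in hiPS10, and 8, 8 and 5 of 8 libraries were closest to one of their own number in H9, HS1 and hiPS10. Between H9 and HS1 the differences correlated at 0.79 to 0.89, between H9 and hiPS10 at -0.24 to 0.38 and between HS1 and hiPS10 at -0.30 to 0.34. Replicates of a group correlated at 0.934 to 0.961 in H9, 0.936 to 0.960 in HS1 and 0.981 to 0.989 in hiPS10. The fit with replicate number as a block is therefore given beside results it changes. For day contrasts and the interaction the block had a term for each line. For line pairs it had 1 term common to all lines, which the hiPS10 replicates do not follow.

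The fits were tested on simulated counts with 200 changed genes per comparison (dispersion 0.02). The simulated difference between replicates of a line was constant over the days, as the block assumes, and changed genes changed alike in every line. The gain with the block was thus built in. It does not show how the block performs where replicate differences vary between days, as in hiPS10. For day 16 against day 13 over 18656 genes, the fit without block recovered 4.48%, 34.3% and 74.2% of genes changed 1.5-, 2- and 4-fold and the fit with block 74.6%, 100% and 100% with 10 false calls. For H9 against HS1 the shares were 11.9%, 53.7% and 87.9% without and 23.9%, 80.6% and 98.5% with the block. In H9 alone, over 17478 genes, none of the changed genes was recovered at any of these sizes without the block, and 14.9%, 80.6% and 98.5% with it, with 6 false calls. In hiPS10 alone, over 17145 genes, the shares were 4.48%, 28.4% and 90.9%. Camera called the 1 changed list and 0 of 30 unchanged ones. The unchanged lists held genes picked at random, with counts drawn independently around each gene's mean. This check therefore does not bear on calls at the preset correlation for lists whose genes vary together.

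The alternatives fixed in advance were DESeq2 (for the interaction its likelihood ratio test), RLE size factors, no filter and a stricter one (1 CPM in 25% of libraries), a replicate block, a minimum fold of 1.5, each line left out, day as a number and each library left out. Added after seeing the data were a correction of each library's trend over exon GC content (spline of 5 degrees of freedom), alone and with the block, a block in H9 and HS1 only, replicate 1 or replicate 2 libraries only in H9 and HS1, and a paired fit of 16 libraries. Camera with the block and an estimated correlation, and the block for line lists, were added then too. Where a group has 0 counts, folds are lower bounds from a floor of 3 counts over the group, set against the pooled counts of the other group. Floors cover counting error only and leave out the spread between replicates. The interval of an odds ratio is over genes, which are not independent replicates.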

Results

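RNA was sequenced from forebrain neural progenitors made on a laminin substrate from 3 human pluripotent lines. H9 is an embryonic stem line, and hiPS10 and HS1 are induced pluripotent lines. Cells were collected at days 13, 14, 15 and 16 of differentiation, with 2 replicate differentiations per line and day. This gave 12 groups of 2 and 24 libraries in all. Total counts ran from 20187172 to 48810080 in the 8 H9 libraries, from 22299462 to 36873141 in the 8 hiPS10 libraries and from 19292295 to 42341716 in the 8 HS1 libraries. Between 23244 and 27389 genes had at least 1 count in a library, and 19062 genes passed the expression filter and were tested. Positions are on hg38.

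A first question for such a protocol is whether the cells carry a forebrain identity and have left pluripotency. OTX2, which marks forebrain and midbrain, had a mean of 402 CPM ± 37.3 (SD, n = 8) in H9, 552 ± 70.5 in hiPS10 and 358 ± 29.4 in HS1. In the same order SIX3, a factor of anterior forebrain and eye, had 55.5 CPM ± 11.2, 175 ± 31.1 and 65.5 ± 12.8. PAX6, a factor of dorsal forebrain progenitors and eye, had 133 CPM ± 14.1, 89.3 ± 25.4 and 88.1 ± 16.0. The neural stem cell factor SOX2 had 727 CPM ± 479, 931 ± 194 and 803 ± 505. The intermediate filament gene NES had 1246 CPM ± 287, 2269 ± 310 and 1121 ± 157. DCX, expressed in migrating young neurons, had 345 CPM ± 142, 174 ± 38.0 and 329 ± 161. The pluripotency factor POU5F1 had 1 count in all H9 libraries together, 2 in hiPS10 and 49 in HS1. NANOG had a mean of 0.370 CPM, 0.384 CPM and 0.694 CPM. EN1, a midbrain and hindbrain gene, had 1, 4 and 5 counts, and HOXB2, a hindbrain gene, had 0, 1 and 0 counts. A count of 0 allows up to 0.0125 CPM in H9 and 0.0135 CPM in HS1 (3 counts over the 8 libraries, counting error only). NKX2-1, a ventral forebrain factor, had 5.07 CPM ± 4.08, 37.4 ± 17.1 and 16.1 ± 16.7.

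The libraries were first compared without regard to group. The first principal component of log2 CPM held 36.7% of the variance and parted replicate 1 from replicate 2 in H9 and HS1, whereas the hiPS10 replicates lay together. The second component held 22.5% and set hiPS10 apart from both other lines, and the third held 12.4% and followed the day. NKX2-1 moved with the first of these differences. In H9 it had 1.42 CPM ± 0.440 in replicate 1 and 8.72 ± 1.74 in replicate 2 (SD, n = 4 days). In HS1 it had 2.43 CPM ± 0.668 and 29.7 ± 12.6, and in hiPS10 49.8 ± 14.4 and 25 ± 7.95. SP8, a factor of forebrain progenitors, was higher in replicate 2 by a log2 difference of 1.34 in H9 and 1.37 in HS1. The forebrain patterning list as a whole went the other way, with a median difference of -0.399 in H9 and -0.387 in HS1. After GC correction these medians were 0.219 and 0.342.

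**Figure D1:**
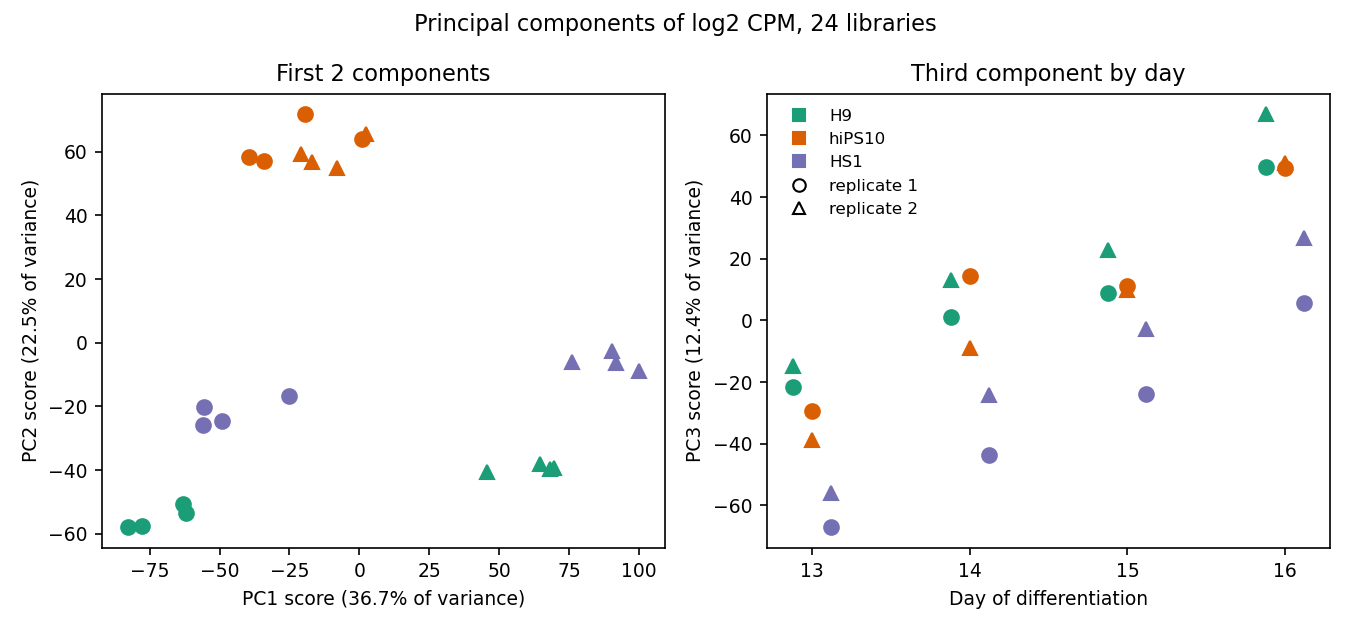
Principal component scores of log2 CPM for 24 libraries, the first against the second component on the left and the third against day of differentiation on the right, with colour for the line and symbol for the replicate. Replicates of H9 and HS1 part along the first component (36.7% of variance), hiPS10 stands apart on the second (22.5%), and the third (12.4%) rises with day.

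The main question of the time course was what changes between day 13 and day 16. LIN28A, an RNA-binding protein of pluripotent and early progenitor cells, had 976 CPM ± 234 at day 13 and 231 ± 72.9 at day 16 (mean ± SD over 6 libraries). SLC17A6, a vesicular glutamate transporter of excitatory neurons, had 4.195 CPM ± 2.04 and 40.2 ± 13.3. SCG2, a secretory granule protein of neuroendocrine cells and neurons, had 1.71 CPM ± 1.08 and 18.2 ± 6.97. HSPH1, a heat shock chaperone, had 265 CPM ± 51.9 and 99.7 ± 7.95. In edgeR's quasi-likelihood test of the mean change over lines, 3478 genes passed a false discovery rate of 0.05 (5619 at an unadjusted p under 0.05). Of these, 2002 rose and 1476 fell, with a median absolute log2 fold change of 0.865. Of the 3478, 3459 (99.5%) had the same sign in all 3 lines, which selection on the mean over these lines itself favours. With the replicate number as a block the count was 9279 (4770 rose and 4509 fell), which included all 3478 in the same direction.

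The protein-coding genes with the largest rises at 5 CPM or more were IL32, a cytokine gene (log2 fold change 4.30, SE 0.33, adjusted p = 5.9e-06), and FSTL5, a secreted glycoprotein gene (4.196, SE 0.60, adjusted p = 0.000248). They were followed by TNFRSF9, a receptor of the tumour necrosis factor family (3.82, SE 0.34, adjusted p = 1e-05), COL1A1, a fibrillar collagen (3.60, SE 0.57, adjusted p = 0.000559), and HGNC:24955, a gene the count tables give by identifier (3.48, SE 0.36). SCG2 rose by 3.44, SLIT1, an axon guidance ligand, by 3.32, PPP1R17, a phosphatase regulatory subunit, by 3.29, SLC17A6 by 3.26 and LRRN3, a leucine-rich repeat neuronal protein, by 3.23. The largest falls were those of LIN28A (-2.10, SE 0.22, adjusted p = 2.75e-05), the metalloproteinase gene ADAMTS19 (-2.02, SE 0.47, adjusted p = 0.00748) and the membrane protein gene TMEM132B (-1.92, SE 0.22). PKDCC, a secreted kinase, fell by 1.80, ID2, an inhibitor of basic helix-loop-helix factors, by 1.60, SHISA6, a modulator of glutamate receptors, by 1.51, TEAD4, a DNA-binding partner of YAP, by 1.49 and KBTBD8, a ubiquitin ligase adaptor, by 1.45. HSPH1 fell by 1.39 (SE 0.10, adjusted p = 3.61e-06) and ALCAM, a cell adhesion molecule, by 1.34. LIN28A lies on chromosome 1, SLC17A6 on chromosome 11, COL1A1 at 50183289 to 50201632 on chromosome 17 and IL32 at 3065297 to 3082192 on chromosome 16.

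**Figure D2:**
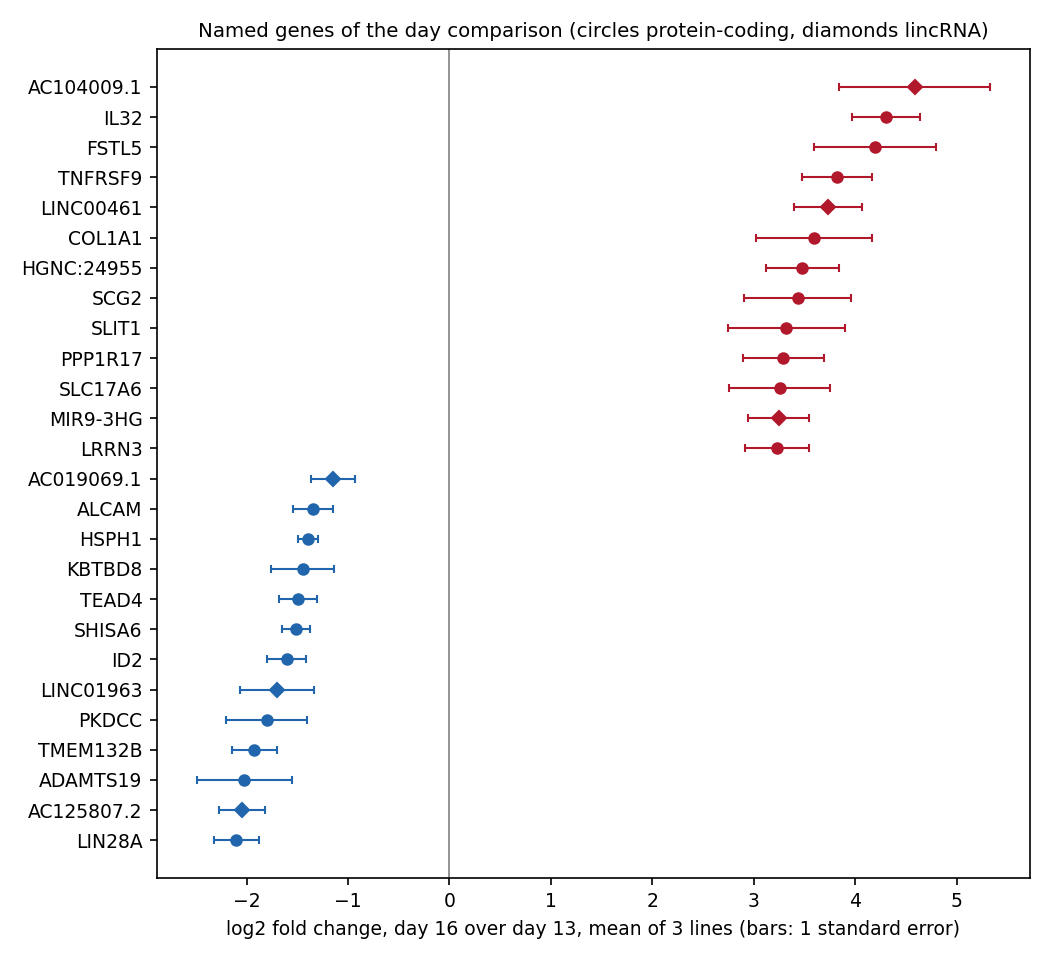
Log2 fold change of day 16 over day 13, mean of 3 lines, for the named protein-coding (circles) and lincRNA genes (diamonds), with bars of 1 standard error from the edgeR fit of 24 libraries. Rises reach 4.59 (AC104009.1) and falls reach -2.10 (LIN28A).

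Genes of neurogenic commitment rose as a group. Of 19 measured, 15 rose and none fell (16 and 0 adjusted over the list alone). The list ranked above other genes by camera (adjusted p = 5.01e-13 with the preset correlation, adjusted p = 0.064 with an estimated correlation). The zinc finger factor MYT1 rose by 2.85 (SE 0.23, adjusted p = 7.27e-06) and NHLH1, a factor of newborn neurons, by 2.59. The intermediate progenitor factor EOMES rose from 10.4 CPM ± 4.36 to 48.7 ± 15.4. Of 20 measured genes of neuronal structure and synapse, 16 rose and none fell (18 and 0 adjusted over the list alone; camera adjusted p = 1.51e-13, adjusted p = 0.064 with an estimated correlation). The glutamate receptor subunit GRIA2 rose by 4.74, the microtubule proteins MAPT and STMN4 by 2.40 and 2.30, and the vesicle fusion protein SNAP25 by 1.62. Of 33 lists, 12 passed at the preset correlation and each of these calls was lost with an estimated one. With the replicate block as well, the neuronal structure list alone passed with an estimated correlation (adjusted p = 0.00634).

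Genes of the cell cycle fell over the same days. In the S phase list 9 of 15 fell and none rose (11 and 0 adjusted over the list alone; camera adjusted p = 4.02e-08, adjusted p = 0.16 with an estimated correlation). The nucleotide synthesis genes fell, RRM1 by 0.74 and TYMS by 0.68, as did the replication licensing gene CDC6 by 1.23 and the sliding clamp PCNA by 0.77. In the G2 and M list 10 of 15 fell and none rose (11 and 0 adjusted over the list alone; camera adjusted p = 1.2e-08, adjusted p = 0.0663 with an estimated correlation). The checkpoint kinase BUB1 fell by 0.84, cyclin CCNB1 by 0.95, the spindle factor TPX2 by 0.83 and the kinase AURKA by 0.93. With the replicate block all 15 genes of each list fell. Heat shock genes gave 3 falls and no rise of 8 measured (3 adjusted over the list alone; camera adjusted p = 0.00916, adjusted p = 0.148 with an estimated correlation). Beside HSPH1 these were HSPA8, which fell by 1.18, and HSP90AA1, which fell by 0.83.

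**Figure D3:**
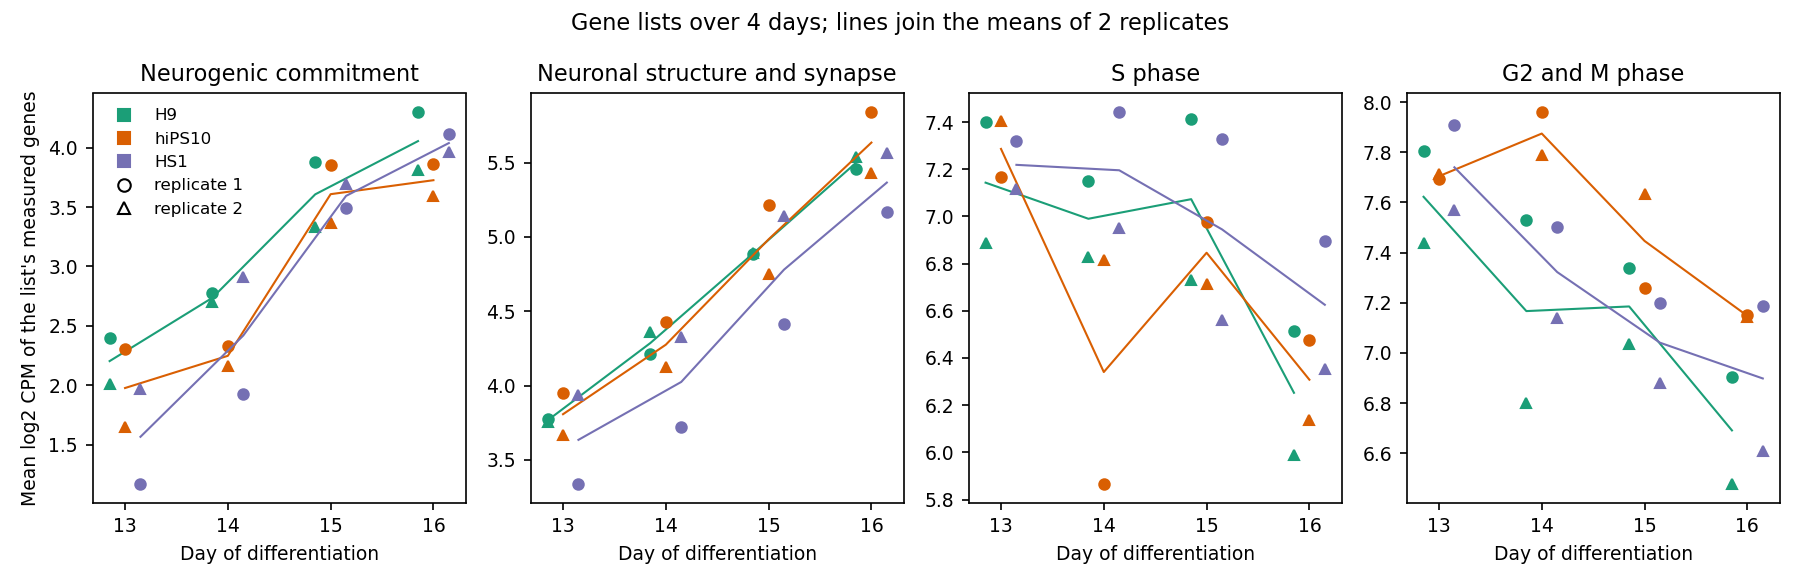
Mean log2 CPM of the measured genes of 4 lists (neurogenic commitment, neuronal structure and synapse, S phase, G2 and M phase) against day of differentiation, 1 point per library, with colour for the line, symbol for the replicate and lines through the means of 2 replicates. The first 2 lists rise from day 13 to day 16 in every line and the 2 cell cycle lists end below their day 13 level in every line.

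Imprinted genes also rose: 7 of 18 passed and none fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00698, adjusted p = 0.064 with an estimated correlation). These included the cyclin-dependent kinase inhibitor CDKN1C (log2 fold change 1.57), MAGEL2 (1.29), the noncoding RNA MEG3 (0.89) and the zinc finger factor PLAGL1 (0.65). Among lists for cells outside the forebrain lineage, neural crest and peripheral neuron genes had 3 rises of 6 (3 adjusted over the list alone; camera adjusted p = 0.00916, adjusted p = 0.064 with an estimated correlation). ISL1, also a factor of forebrain and motor neurons, rose from 0.169 CPM ± 0.123 to 2.92 ± 0.989, and SNAI2 by 1.51. Mesenchymal genes had 3 rises of 8 (3 adjusted over the list alone; camera adjusted p = 0.0177, adjusted p = 0.0663 with an estimated correlation). COL1A2 rose by 2.08 and POSTN by 1.27, beside COL1A1. Glial genes had 2 rises of 6 (2 adjusted over the list alone; camera adjusted p = 0.0361, adjusted p = 0.148 with an estimated correlation, adjusted p = 0.0598 with the block). These were MBP, up by 1.96, and OLIG2, up by 2.61. Of 4 mesoderm and endoderm genes GATA6 rose, by 2.35 at a mean of 0.385 CPM. The list passed (1 adjusted over the list alone; camera adjusted p = 0.039, adjusted p = 0.177 with an estimated correlation, adjusted p = 0.0927 with the block).

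Regional identity genes moved in both directions. Of 20 forebrain patterning genes 3 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.165). The dorsal forebrain factor EMX2 rose by 1.06, while the anterior factors SIX6 and SIX3 fell by 2.19 and 0.56 and NR2F2 by 0.81. Of 10 ventral forebrain and GABAergic genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.891). GSX2, a factor of the ganglionic eminences, rose from 0.259 CPM ± 0.167 to 3.40 ± 1.70 and DLX1 from 0.193 ± 0.107 to 1.55 ± 0.363. Of 10 cortical hem and choroid plexus genes the WNT agonist RSPO3 rose by 2.65 and LMX1A, a factor of the hem, fell from 0.711 CPM ± 0.470 to 0.125 ± 0.170 (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.891). Of 18 neural stem and radial glia genes 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.748). VIM rose by 1.02, SOX9 by 0.67 and HOPX by 3.25 at a mean of 0.274 CPM, whereas PROM1 fell by 0.68. Of 9 pluripotency genes LIN28A and SALL4 fell, by 2.10 and 0.48, and LEFTY2 rose by 1.55 (1 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.0649).

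The remaining lists were signalling, stress, metabolic and other cell type genes. Of 12 FGF and ERK targets 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.0649, adjusted p = 0.0266 with the block, lost there at an estimated correlation with adjusted p = 0.349). ETV5 fell by 1.08 and SPRED2 by 0.43, whereas the immediate early genes EGR1 and FOS rose by 1.20 and 1.17. The rise of EGR1 was mainly that of hiPS10 (0.53 in H9, 2.93 in hiPS10 and -0.03 in HS1). Of 14 Notch pathway genes HEY1 and DLL3 rose by 1.40 and 1.42 and DTX4 fell by 0.50 (2 and 1 adjusted over the list alone; camera adjusted p = 0.599). Of 8 WNT targets ZNRF3, NKD1 and LGR5 fell by 0.47, 0.79 and 0.70 (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.239). Of 11 BMP and TGF-beta targets MSX2 and LEFTY2 were among those that rose and ID2 was among 2 that fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.827). Of 13 SRF and YAP targets CTGF rose by 0.82 and AMOTL1, TPM1 and LATS2 fell by 0.40, 0.80 and 0.36 (4 and 4 adjusted over the list alone; camera adjusted p = 0.693). The list of 6 retinoic acid response genes did not pass (camera adjusted p = 0.689). In the hypoxia and glycolysis list NDRG1 and PGK1 rose by 2.23 and 0.44, 2 of 14 (3 adjusted over the list alone; camera adjusted p = 0.056). In the p53 list BBC3 and CDKN1A rose by 0.82 and 1.34, 2 of 11 (3 adjusted over the list alone; camera adjusted p = 0.325). Of 13 integrated stress genes DDIT4 and HERPUD1 rose by 0.82 and 0.33 and PSAT1 and HSPA5 fell by 0.80 and 0.52 (2 and 3 adjusted over the list alone; camera adjusted p = 0.827).

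Of 15 cholesterol synthesis genes FDPS and SQLE fell by 0.43 and 0.32 (2 adjusted over the list alone; camera adjusted p = 0.0558, adjusted p = 0.0168 with the block, lost there at an estimated correlation with adjusted p = 0.349). Of 13 mitochondrially encoded genes MT-CYB was the 1 that fell, by 0.45 (0 by edgeR adjusted over the list alone; 10 fell with the block; camera adjusted p = 0.039, adjusted p = 0.332 with an estimated correlation). Of 10 replication-dependent histone genes, which are incompletely captured in polyadenylated RNA and share reads with near-identical copies, HIST2H2BE had the 1 rise (1 adjusted over the list alone; camera adjusted p = 0.238). Among 10 genes variably expressed or silenced in induced pluripotent lines, DPP6, TMEM132D and CAT rose by 1.27, 1.46 and 0.56 and PTPRT fell by 1.54 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0786). Of 5 endothelial genes KDR and TIE1 rose by 1.06 and 1.71 and TEK fell by 1.24 (2 and 1 adjusted over the list alone; camera adjusted p = 0.599). EYA2 was the 1 of 7 surface ectoderm genes that rose, by 0.99 (1 adjusted over the list alone; camera adjusted p = 0.681). EGR2 was the 1 of 4 midbrain, hindbrain and spinal cord genes that rose, by 2.88 at a mean of 0.306 CPM (1 adjusted over the list alone; camera adjusted p = 0.599). Of 5 hedgehog targets 0 passed in edgeR, over all genes or adjusted over the list alone, and with the block 1 rose and 1 fell. PTCH1 had a log2 fold change of -0.31 (SE 0.18; camera adjusted p = 0.827 for the list). The hedgehog, SRF and YAP, integrated stress, and midbrain, hindbrain and spinal cord lists had a median, a mean and a camera direction that were not all of 1 sign.

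Long noncoding RNA genes between protein-coding genes (lincRNAs) were a class of their own in the design. LINC00461, expressed in developing brain, rose from 5.29 CPM ± 2.13 at day 13 to 71.3 ± 32.1 at day 16 (log2 fold change 3.73, SE 0.34, adjusted p = 1e-05). AC104009.1 rose by 4.59 and MIR9-3HG, a host gene of the neural microRNA miR-9, from 0.397 CPM ± 0.214 to 3.69 ± 0.421. AC125807.2 fell from 10.1 CPM ± 1.37 to 2.43 ± 0.470, LINC01963 by 1.70 and AC019069.1 by 1.15. Of 1333 lincRNA genes tested by edgeR, 209 changed, of which 185 (88.5%) rose, and with the block 488 changed (392 rose, 96 fell). They passed less often than other genes, at 15.7% against 18.4% (odds ratio 0.823, 95% interval 0.703 to 0.959, Fisher's exact test, two-sided p = 0.0112), and with the block at 36.6% against 49.6% (odds ratio 0.587). Their median level was 0.815 CPM against 20.5 CPM for protein-coding genes. With a stricter expression filter 126 of 699 passed, at 18% against 20.3% of other genes (odds ratio 0.861, Fisher's exact test, two-sided p = 0.148). The odds ratio was near that of the usual filter, so level is not shown to be the cause. In the fixed list of long noncoding RNAs of neural or pluripotent cells, 5 of 14 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0257, adjusted p = 0.521 with an estimated correlation). MIAT rose from 132 CPM ± 27.4 to 586 ± 224 and LINC-PINT by 1.16.

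Single days were compared to see when these changes came. From day 13 to day 14 the chaperone HSPH1 went from 265 CPM ± 51.9 to 147 ± 18.9 and IL32 from 0.776 ± 0.530 to 3.003 ± 1.22. EOMES stayed at 10.4 CPM until day 14 and had 33.7 ± 7.19 at day 15. LIN28A had 759 CPM ± 234 at day 14, 448 ± 130 at day 15 and 231 ± 72.9 at day 16. In the neurogenic commitment list the median log2 change was 0.69, 1.16 and 0.36 over the 3 steps. By edgeR 0, 7 and 1 genes of the list were called, and 8, 16 and 7 with the block. In the S phase list it was -0.34, 0.11 and -0.57, with 0, 0 and 4 genes called and 6, 0 and 14 with the block. Its first 2 steps depend in part on 1 library, hiPS10 day 14 replicate 1, with a list mean of 5.87 in log2 CPM against 6.82 in its replicate. Day 14 against day 13 gave 20 genes (17 rose, 3 fell; 1534 at an unadjusted p under 0.05). Day 15 against day 14 gave 259 (151 rose, 108 fell; 2061) and day 16 against day 15 gave 465 (262 rose, 203 fell; 2811). The 3 that fell first were HSPH1 (-0.84), SHISA6 (-1.05) and NETO2, an auxiliary subunit of glutamate receptors (-0.53), the last chosen after its values were seen. With the replicate block the counts were 2285 (1280 rose, 1005 fell), 3011 (1485 rose, 1526 fell) and 5260 (2604 rose, 2656 fell), so the balance turned in the later 2 steps. The first count was 1 without HS1 day 13 replicate 2 and 172 without hiPS10 day 14 replicate 2. The second was 65 without HS1 day 14 replicate 1, and the third 60 without hiPS10 day 16 replicate 2.

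Each line was then examined alone, to see whether the lines change alike. The median change of the neuronal structure list from day 13 to day 16 was 1.46 in H9, 1.73 in hiPS10 and 1.59 in HS1, and that of the G2 and M list was -0.98, -0.53 and -0.83. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.815 between H9 and hiPS10 (16613 genes, Spearman rho = 0.793). It was 0.829 between H9 and HS1 (17114 genes, rho = 0.802) and 0.813 between hiPS10 and HS1 (16798 genes, rho = 0.795). The signs were the same for 82.3%, 82.6% and 82.0% of genes. In hiPS10 2258 genes changed (1408 rose, 850 fell; 5203 at an unadjusted p under 0.05). The count in that line was 411 and 271 without replicates 1 and 2 of day 13, 3948 and 3918 without those of day 14, and 777 and 722 without those of day 16. In H9 and in HS1 edgeR called 0 genes (1586 and 1582 at an unadjusted p under 0.05), DESeq2 605 and 512, and edgeR with the replicate block 4796 and 5633. With the block, 1717 genes rose in both H9 and HS1 where 375 were expected by chance. In both lines 1965 fell where 389 were expected, and 4 changed in opposite directions. The expected numbers assume independent lines and an equal chance of a call for every gene. Same-numbered libraries of H9 and HS1 shared a difference, so the excess is not a measure of a shared day effect alone.

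The line by day interaction tested whether the change from day 13 to day 16 differed between lines. SYT11, a synaptotagmin, had log2 fold changes of 1.87 in H9, 0.69 in hiPS10 and 0.70 in HS1, and UNC13C, a synaptic vesicle priming protein, 2.28, 0.71 and 0.23. EGR1 had 0.53, 2.93 and -0.03, and ANGPT2, an angiopoietin, -0.21, 3.68 and 2.15. These were the 4 genes that passed in edgeR with the replicate block (adjusted p = 0.0254 each; 895 at an unadjusted p under 0.05), and they were named after their values were seen. Without the block edgeR called 0 genes (168 at an unadjusted p under 0.05), and a likelihood ratio test in DESeq2 called 4. Whether those DESeq2 calls are the genes named here was not examined.

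Differences between lines, averaged over the 4 days, address how far cells of different origin reach the same state. Each line had 2 differentiation replicates, and same-numbered libraries of H9 and of HS1 shared a difference over the days. The 8 libraries of a line are thus not 8 independent replicates. The fits of line pairs count them as such, so their standard errors and p-values are too small to an unknown degree. Several imprinted genes were high in 1 line and low or near 0 in another. The paternally expressed zinc finger gene PEG3 (chromosome 19, 56810083 to 56840728) had 427 CPM ± 103 (SD, n = 8) in hiPS10, 0.132 ± 0.181 in H9 and 1.23 ± 0.504 in HS1. Its neighbour MIMT1, a lincRNA, had 10.9 CPM ± 1.503 in hiPS10, at least 869-fold more than in H9, where it had 0 counts (floor of 3 counts over the 8 libraries). ZIM2, whose interval contains PEG3, had 0.600 CPM ± 0.167 in hiPS10 and 0 counts in H9 and in HS1. The maternally expressed noncoding RNA MEG3 (chromosome 14, 100779410 to 100861031) had 1216 CPM ± 275 in HS1, 26.7 ± 8.40 in H9 and 31.7 ± 11.5 in hiPS10. The neighbouring MEG8 and MEG9 had means of 21.4 and 16.2 CPM in HS1, against 0.749 and 0.504 in H9 and 0.703 and 0.402 in hiPS10. NNAT, paternally expressed and active in developing brain (chromosome 20, 37521215 to 37523693), had 588 CPM ± 380 in H9, 340 ± 132 in hiPS10 and 7.21 ± 4.46 in HS1. BLCAP, the gene around it, had 129, 84.8 and 141 CPM.

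**Figure D4:**
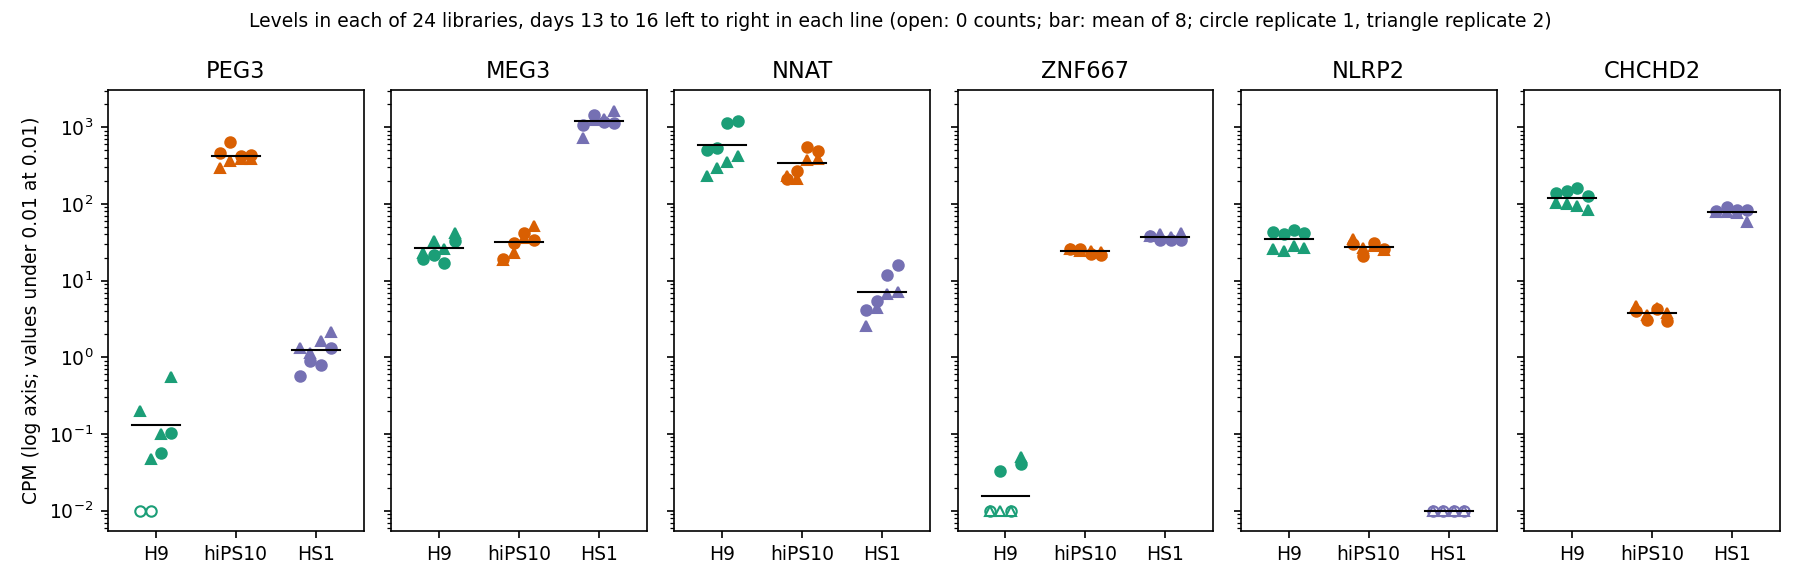
CPM on a log axis for 6 genes in each of 24 libraries, by line, with days 13 to 16 from left to right within a line, circles for replicate 1, triangles for replicate 2, open symbols for 0 counts, values under 0.01 CPM drawn at 0.01 and a bar at the mean of 8 libraries. PEG3 is high in hiPS10 (427 CPM), MEG3 in HS1 (1216 CPM) and NNAT in H9 and hiPS10 (588 and 340 CPM), whereas ZNF667 is near 0 in H9, NLRP2 has 0 counts in HS1 and CHCHD2 is low in hiPS10 (3.84 CPM).

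Outside the imprinted genes, H9 and hiPS10 differed most in genes that were low or near 0 in 1 of them. CHCHD2, a mitochondrial protein (chromosome 7, 56101569 to 56106576), had 119 CPM ± 28.4 in H9 and 3.84 ± 0.591 in hiPS10 (log2 difference 4.96, SE 0.17, edgeR adjusted p = 8.71e-11). ZNF667, a zinc finger gene (chromosome 19, 56439325 to 56478065), had 0.0154 CPM ± 0.0218 in H9 and 24.1 ± 1.57 in hiPS10. Its antisense neighbour ZNF667-AS1 had 1 count in H9 and 26.7 CPM in hiPS10, and nearby ZNF471 had 0.558 CPM and 32.8 CPM. CEBPZOS had 0.0616 CPM and 102 CPM, CCDC152 0.108 CPM and 114 CPM, and ZNF736 had 3 counts in H9 and 11.1 CPM in hiPS10. GRPR, the receptor of gastrin-releasing peptide, was higher in H9 by 3.05, SETD9, a methyltransferase-like gene, by 2.79, the ligand gene WNT4 by 2.77 and SLITRK2, a neuronal membrane protein, by 2.75. The lincRNAs AC016205.1, LINC02562 and UBBP4, a pseudogene with ubiquitin gene copies that can share its reads, were higher in H9 by 6.27, 3.71 and 3.87. BX322639.1 had 0.0255 CPM in H9 and 34.02 CPM in hiPS10, and MIR4458HG had 0 counts in H9 and was at least 610-fold higher in hiPS10.

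Regional and signalling genes differed between these lines as well. SIX3 was lower in H9 than in hiPS10 (log2 difference -1.66, SE 0.11, edgeR adjusted p = 5.15e-08), as were NKX2-1 (-2.86, adjusted p = 0.0161), OTX2 (-0.45) and NES (-0.87). The forebrain factor DMRTA2 was higher by 2.03. WNT targets LGR5, AXIN2 and ZNRF3 were higher in H9 by 2.62, 0.93 and 0.89, and the hedgehog targets GLI1 and PTCH1 were lower (-3.03 and -0.65). Of 8 WNT targets 4 were higher and 1 lower, and of 5 hedgehog targets 1 was higher and 4 lower, and neither list passed (camera adjusted p = 0.171 each). The retinoic acid binding protein gene CRABP2 (-1.40) and the radial glia gene FABP7 (-1.09) were lower in H9, while the neuronal genes CNTN2 and DCX were higher by 1.96 and 0.94. Of 20 neuronal structure genes 4 were higher and 4 lower (camera adjusted p = 0.674), and of 20 forebrain patterning genes 5 were higher and 4 lower (camera adjusted p = 0.97). CAT, the catalase gene, had 0.736 CPM in H9 and 20.6 CPM in hiPS10. In all 6271 genes differed (3620 higher and 2651 lower in H9; 7995 at an unadjusted p under 0.05), with a median log2 difference over all genes of 0.10. Line and processing batch cannot be told apart for hiPS10, whose libraries were counted apart from the others.

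Mitochondrially encoded transcripts were the 1 list that set hiPS10 apart from both other lines. They took 10.0% ± 1.71 of counts in hiPS10 (SD, n = 8), 4.52% ± 0.446 in H9 and 3.66% ± 0.641 in HS1. Of 13 genes 12 were higher in hiPS10 than in H9 (12 adjusted over the list alone; camera adjusted p = 3.09e-08, adjusted p = 0.0793 with an estimated correlation). Also 12 were higher than in HS1 (12 adjusted over the list alone; camera adjusted p = 5e-10, adjusted p = 0.0392 with an estimated correlation). With the block this call was lost at an estimated correlation (adjusted p = 0.0731), and no line list passed there. MT-CYB differed by -1.54, MT-ND5 by -1.37, MT-CO3 by -1.30 and MT-ATP6 by -1.64 between H9 and hiPS10. With the block the G2 and M list (9 of 15 lower in H9, adjusted p = 0.0448) and the hypoxia and glycolysis list (9 of 14 higher, adjusted p = 0.0423) passed between H9 and hiPS10. Both were lost with an estimated correlation (adjusted p = 0.709 and adjusted p = 0.689) and with the GC correction beside the block (adjusted p = 0.0658 and adjusted p = 0.078).

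H9 and HS1 differed in fewer genes in the fit of all 24 libraries. They share a count run, but HS1 was taken from an earlier series, so line and batch cannot be told apart here either. NLRP2, an innate immunity gene also needed in oocytes (chromosome 19, 54953130 to 55001142), had 34.5 CPM ± 9.02 in H9, 27.9 ± 4.28 in hiPS10 and 0 counts in HS1, which is at least 2040-fold less than in hiPS10. NNAT was higher in H9 by 6.42 (SE 0.38, edgeR adjusted p = 2.63e-08), the zinc finger gene ZNF714 by 4.29, the melatonin-related receptor gene GPR50 by 2.34 and RGPD2, which has near-identical copies, by 2.503. ZNF667 (-11.56), CEBPZOS (-11.32), ZNF502 (-10.17) and CCDC152 (-8.92) were lower in H9, and ZNF736 had 27.8 CPM in HS1. Among lincRNAs LINC01139, AL590705.1 and DDX11L2, a gene with near-identical copies, were higher in H9 by 5.66, 3.60 and 3.65. BX322639.1 was lower (-10.67), and MIR4458HG and FAM239C, with 0 counts in H9, were at least 405-fold and 506-fold higher in HS1. The imprinted H19 was higher in H9 by 2.67, CAT was lower (-4.38) and the membrane protein gene TMEM132C higher by 5.23.

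The SRF and YAP, mesoderm and endoderm, BMP and TGF-beta, and cortical hem lists ranked higher in H9 than in HS1 by camera at the preset correlation. The contractile genes TAGLN and ACTA2 were higher by 1.16 and 1.20 and CTGF by 0.73. These were the 3 of 13 SRF and YAP targets that passed (6 adjusted over the list alone; camera adjusted p = 0.00118, adjusted p = 0.234 with an estimated correlation). GATA6, GATA4 and AFP, 3 of 4 mesoderm and endoderm genes and all under 1 CPM, were higher by 1.98, 2.81 and 1.41 (3 adjusted over the list alone; camera adjusted p = 0.00228, adjusted p = 0.225 with an estimated correlation). MSX1 and MSX2, 2 of 11 BMP and TGF-beta targets, were higher by 1.31 and 2.10 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0105, adjusted p = 0.225 with an estimated correlation). MSX1 was also the 1 gene of 10 that passed in the cortical hem list (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0238, adjusted p = 0.225 with an estimated correlation). With the block the mesenchymal (adjusted p = 0.0377), hypoxia (adjusted p = 0.0481) and mitochondrial lists (adjusted p = 0.0481) passed as well. They too were lost with an estimated correlation (adjusted p = 0.166, adjusted p = 0.452 and adjusted p = 0.428). With the GC correction beside the block the hypoxia (adjusted p = 0.0985), BMP and TGF-beta (adjusted p = 0.0921) and cortical hem calls (adjusted p = 0.0992) were lost. In all 1248 genes differed (643 higher and 605 lower in H9, and 2983 at an unadjusted p under 0.05), and 2235 with the block. A fit of these 16 libraries with day and replicate number paired gave 7743. It counts the days as independent, which they are not in these lines.

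Between hiPS10 and HS1, PEG3, MEG3, NNAT and NLRP2 differed as given above. CHCHD2 was lower in hiPS10 (log2 difference -4.37, SE 0.16, edgeR adjusted p = 7.48e-10), as were FSIP2, a sperm sheath protein gene (-3.30), SLITRK2 (-3.21) and HIRA, a histone chaperone (-2.79). TMSB4X, an actin-binding peptide gene with processed copies, had 370.0 CPM ± 78.3 in hiPS10 and 2213 ± 1176 in HS1. YJEFN3 was higher in hiPS10 by 2.94, ZNF714 by 4.45 and AC069277.1 by 4.19, while AL590705.1 had 6.53 CPM and 0.202 CPM and MEG9 was lower (-5.34). SIX3 was higher in hiPS10 by 1.41, OTX2 by 0.62, NES by 1.01, GLI1 by 2.05 and TAGLN by 1.86, and the heat shock gene HSPA1A, which has a near-identical copy, by 1.47. LGR5 (-2.23), TYMS (-0.66) and PCNA (-0.60) were lower. In all 5923 genes differed (2501 higher and 3422 lower in hiPS10, and 7759 at an unadjusted p under 0.05). With the block 8897 did, but its replicate term is common to all lines and the hiPS10 replicates do not follow it. The balance turned with the GC correction, to 3921 higher and 3714 lower.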

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

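The cell mix, imprint state and shared read tests, the GC, depth and batch tests of mitochondrial transcripts, and the splits of the 3-day change, of the interaction and of the paired fit were chosen after the results were seen; the other tests were chosen before, with a GC correction added once the data had been seen.

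Of the changes from day 13 to day 16, those of SYT11, EGR1, ANGPT2 and UNC13C differed between lines in the interaction test with the replicate block (adjusted p = 0.0254 each), and without the block each had an adjusted p of 1. SYT11 and UNC13C had their largest rise in H9 (log2 fold change 1.87 and 2.28), and EGR1 and ANGPT2 in hiPS10 (2.93 and 3.68). In a fit of 12 libraries with each same-numbered pair as a block the interaction gave 0 genes, so the 4 calls were lost there, while the highest among the 15 possible splits was 19; 15 splits are too few for a share under 0.05. With the GC correction and the block 28 genes passed.

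Replicates 1 and 2 of H9 and HS1 differed in the same genes, with r = 0.93 across genes between the lines' mean differences. A smooth trend over exon GC content is argued against as the whole cause, since after its correction r was 0.86. The spread of the difference over genes (SD) went from 0.988 to 0.694 in H9 and from 1.01 to 0.719 in HS1. A GC bias that this trend does not capture could still be shared by both lines, and r cannot tell it from another cause. Thinning every library to the lowest total left 0.997 of the spread over genes of at least 5 CPM. Thinning keeps each library's proportions and could hardly shrink the spread, so this does not decide on depth. Totals, looked at after the results, argue against depth in HS1. There replicate 2 had the larger total at days 13 and 14 and the smaller at days 15 and 16. Its replicate differences still correlated at 0.79 to 0.88 between days. A different mix of cells stays open, by a rule made stricter after its value was seen: the ventral forebrain list was higher in replicate 2 after correction by a median of 0.519 in H9 and 0.832 in HS1, but by 0.0619 and 0.388 before, and its members go both ways (lower quartiles -0.127 and -0.387; SIX6 -0.88 and NKX2-1 3.72 in H9). A batch of library preparation or of medium shared by same-numbered cultures may also underlie it, and neither is given in the sources used here.

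Mitochondrial transcripts took a larger share of counts in hiPS10 than in either other line. The difference did not shrink with GC correction (median log2 difference 1.55 before and 1.63 after), and it does not follow depth, since the lowest hiPS10 share was 7.4% and the highest elsewhere 5.28% at totals in the same range. A general rise of respiratory chain transcripts is argued against by the 75 nuclear-encoded subunits, with a median of -0.0392 (quartiles -0.456 and 0.669). Since 0 hiPS10 libraries share a count run with another line, a batch of hiPS10 cannot be told apart from the line. A difference between the lines themselves stays open as untested.

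Imprinted genes were high in 1 line and low (MEG3, NNAT) or near 0 (PEG3) in another. The smallest absolute log2 difference among PEG3, MEG3 and NNAT was 5.32 after GC correction with the block, so GC bias is argued against. Shared reads would not raise the neighbours, yet MIMT1 in hiPS10 and MEG8 and MEG9 in HS1 differed between these lines by at least 4.92. All 3 neighbours were above every library of the other lines, as a change in the imprint state of the whole domain would give, and this stays open as a hypothesis formed on these data. The paternally expressed DLK1 and RTL1 beside MEG3 did not stand apart in HS1 (1030 and 4.8 CPM, against 1610 and 9.56 in H9 and 702 and 7.4 in hiPS10), and allele use was not examined.

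Splits of the samples show how far chance can account for the counts. For day 16 against day 13, 2 of 100 splits gave as many as the 3478 genes, the real split among them. The highest other, 4574, followed replicate number in H9 and HS1, and with the block the counts were 9279 and 3786. Day 14 against day 13 gave 20 against 0 (1 of 60) and day 15 against day 14 gave 259 (2 of 60). In the latter the higher split, 5281, followed replicate number (3011 against 1174 with the block). These shares are under 0.05, but the splits regrouped each line independently of the others. Same-numbered libraries of H9 and HS1 shared a difference, and splits that keep them together were not run. Chance was therefore not excluded for these day comparisons either. H9 against hiPS10 gave 6271 against 0 (1 of 60) and hiPS10 against HS1 5923 against 0 (1 of 60). Those splits moved libraries within each day, although same-numbered libraries of H9 and of HS1 shared a difference over the days. Splits of whole replicates, 2 per line, are too few for a share under 0.05, so chance was not excluded for these pairs. Chance cannot be excluded without the block for day 16 against day 15 (465; 5 of 60), where the other 4 splits, up to 9028, all followed replicate number, and with the block the counts were 5260 and 1503. Neither can it for H9 against HS1 (1248; 7 of 60). There the highest other, 13247, followed replicate number, and the highest of the rest, 11823, did not wholly follow it. In the paired fit of 16 libraries the real split gave 7743 and the highest other 3788.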

How the results depend on the processing

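Alternatives with the GC correction, the block in H9 and HS1 only, 1 replicate of H9 and HS1, and the paired fit were chosen after seeing the data, as were the block for line lists and fold change correlations and, for day lists, the block with an estimated correlation. The called named genes were reversed in 0 of the fits checked, but not every alternative was checked for every gene. In most of those fits only 1 library was left out. Genes named for the largest changes had been picked for the same sign in every line, or for no overlap between lines. Few reversals were thus likely from the start, and their absence says little about robustness. Weaker results, past the threshold no longer, made up 399 of 4315 fits for the day comparison (59 of 111 genes), 251 of 4153 for H9 against hiPS10 (65 of 119), 171 of 2027 for H9 against HS1 (28 of 55) and 224 of 3838 for hiPS10 against HS1 (57 of 110). The cause was not tested except where fewer libraries or genes were used. The levels of the identity markers moved in 0 of 324 fits by more than the SD over the libraries of a line. Most of these fits left out 1 library, which cannot move a line's mean that far, so they do not bear on robustness. LincRNAs had a median of 0.815 CPM.

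With the replicate block the counts were 9279 for day 16 against day 13, 2285, 3011 and 5260 for the 3 steps, 4 for the interaction, 2235 for H9 against HS1, 8897 for hiPS10 against HS1, 4796 in H9 alone and 5633 in HS1 alone. Line lists past the threshold were 11 with it, lincRNAs 488, and fold change r was 0.814, 0.83 and 0.814 (H9 with hiPS10, H9 with HS1, hiPS10 with HS1), against 0.867, 0.913 and 0.877 at 5 CPM or more. With a block in H9 and HS1 only they were 8924, 1662, 2604, 4710 and 3 (interaction). With the GC correction the steps gave 103, 527 and 1095 and H9 alone 145. With the GC correction and the block the values were 9996, steps 2823, 3912 and 6461, interaction 28, H9 against hiPS10 10406, H9 against HS1 2717, hiPS10 against HS1 10035, H9 alone 6284 and HS1 alone 6179. The paired fit of H9 and HS1 gave 7743, and 6170 with the GC correction.

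DESeq2 gave 288, 747 and 1160 for the steps, 4 for the interaction, 605 in H9 alone and 512 in HS1 alone. Without a filter the first and last step had 105 and 290, the interaction 8 and H9 alone 38, and the stricter filter left 126 lincRNAs. At a minimum fold of 1.5 the counts were 892 (day 16 against day 13; 790 rose, 102 fell), 1883 (H9 against hiPS10), 509 (H9 against HS1; 218 higher, 291 lower in H9, so the balance turned) and 1559 (hiPS10 against HS1). Day 16 against day 13 gave 2014 without H9, 1413 without hiPS10 and 1976 without HS1. With day as a number H9 had 188, hiPS10 1467 and HS1 133. With replicate 1 libraries only in H9 and HS1 the first and last step gave 2 and 192, H9 against hiPS10 10721 and hiPS10 against HS1 9273; with replicate 2 only the steps gave 40, 150 and 185 and these pairs 10766 and 11531. With an estimated correlation camera called 0 day lists (lowest adjusted p = 0.064) and 1 line list, and 1 day list with the block.

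Leaving out each library in turn gave 2608 to 3621 for day 16 against day 13, 1 to 172, 65 to 391 and 60 to 590 for the steps, 5369 to 6449 for H9 against hiPS10, 1008 to 1337 for H9 against HS1, 4970 to 6117 for hiPS10 against HS1, 0 to 0 for the interaction, H9 alone and HS1 alone, and 271 to 3948 in hiPS10 alone. A group left with 1 library was assumed to vary like the others. Of 24 such fits 21, 11 and 14 moved the steps by more than 1.5 times.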

Other observations

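The tests in this part are of values chosen after they were seen.

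CTGF, EGR1 and SLC2A3 had higher means at days 14 and 16 than at days 13 and 15, with SDs that overlap between days 13 and 14 and, for SLC2A3, between all days. CTGF, a target of YAP, had 156 CPM ± 96.7 at day 13, 286 ± 136 at day 14, 110 ± 17.6 at day 15 and 257 ± 44.4 at day 16 (mean ± SD over 6 libraries). The immediate early gene EGR1 had 6.26 CPM ± 5.00, 13.2 ± 7.92, 4.27 ± 0.960 and 13.2 ± 7.45. The glucose transporter gene SLC2A3 had 186 CPM ± 40.2, 257 ± 102, 152 ± 39.5 and 260 ± 72.6. Both day 16 libraries lay above both of day 13 in 1 line for CTGF and for EGR1, and in 2 lines for SLC2A3. From day 13 to day 14 none of the 3 passed without the block (adjusted p = 0.166, adjusted p = 0.105 and adjusted p = 0.539), and all did with it (adjusted p = 0.00389, adjusted p = 0.000491 and adjusted p = 0.018). TPM1, a tropomyosin gene, took another course, with 1238 CPM ± 378 and 1239 ± 423 at days 13 and 14 and 609 ± 96.4 and 718 ± 146 at days 15 and 16. Medium was kept from replating until day 14 and then renewed, per the labels.

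No list or enrichment was tested for the 17 genes that rose by day 14. Among them were the annexin gene ANXA1 (log2 fold change 0.94), S100A10 (1.11), CAV2, a caveolin (1.32), EMP1 (1.21), the tight junction gene CLDN1 (1.02), the semaphorin receptor NRP2 (1.13), the ligand gene TGFB2 (0.83) and the protease-activated receptor F2RL1 (1.35). All 20 genes called at that step were also called from day 13 to day 16 in the same direction. Of 259 called from day 14 to day 15, 167 were called over the whole course, 144 of them in the same direction, and of 465 called from day 15 to day 16 all 420 shared ones were.

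In replicate 1 of H9 and HS1, genes with exon GC content over 55% were higher than in replicate 2 by a median log2 of 1.23 and 1.27, and those under 42.1% were lower by -0.529 and -0.544. In hiPS10 the values were 0.128 and -0.0364. The Spearman correlation of the replicate difference with GC content across genes was 0.58 to 0.73 over the 4 days in H9, 0.59 to 0.70 in HS1 and -0.40 to 0.42 in hiPS10.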
